A study of Danio rerio with 18 samples.

How the data were processed

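RNA of whole zebrafish embryos was measured on 18 Affymetrix arrays, 1 array per sample. Wild-type embryos had been injected at the 1 to 2 cell stage with a locked nucleic acid (LNA) oligonucleotide against the microRNA mir-34 or with a mock LNA, and RNA was taken 1, 7 or 24 hours after fertilization (hpf). An LNA oligonucleotide pairs tightly with a small RNA and blocks it. The 6 groups of 3 arrays were taken from the sample labels, which call the 3 arrays of a group biological replicates. How many embryos went into a sample, and whether replicates came from different clutches, is not given in the sources used here. Per the labels' protocols, the embryos of 7 and 24 hpf were freed from the chorion by hand, RNA was extracted with Trizol and biotin-labelled cRNA was made from 6 ug of total RNA.

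The deposited values are on a log2 scale, with 1 value for each of 15617 probe sets on each array. The scale was read from the values: the lowest deposited log2 value was -3.32, which is the base 2 logarithm of a signal of 0.1. The submitters' processing notes name GCOS, the Affymetrix scanning and signal software, without a version. The probe summary, the background correction and the normalization method are not given in the sources used here. The deposited distributions were nearly equal over the 18 arrays, with medians between 3.67 and 3.68 over all values of an array, and 95th percentiles between 7.93 and 7.98 over the probe sets with no missing value, so a difference between groups is relative to the other probe sets of the same arrays and a change in total RNA per embryo cannot be read from it. Such scaling can also turn a one-sided change into changes of both signs. The depth of an array has no count behind it, and the precision is limited by 3 arrays per group. In all, 131 values were missing, in 115 probe sets, and were left missing. The table used holds no detection calls, so low levels are not told apart from background, and a log2 difference from such a level has no exact size; values with 16 added to the signals before the logarithm are given beside some of them.

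Probe sets were named from the platform annotation given for this work. Of the 15502 probe sets that are not Affymetrix controls, 10795 had 1 gene symbol, 135 had several and 4572 had none. Symbols were checked by Entrez number against NCBI's RefSeq gene table of assembly GRCz12tu, which matched 10711 probe sets and updated 1 symbol. No coordinates were used. List entries were matched to the gene that carries the symbol in that table, and through older names only where no gene carries it. This matching was tightened after the results had been seen, which took 12 genes out of 7 lists that an older name had brought in for another gene. A probe set with several symbols or none is counted and not named. Where a gene had several probe sets (1539 of 8793 genes), the one with the highest mean over the 18 arrays stood for it, and disagreement of the others is stated.

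Comparisons were fitted with limma 3.58.1 in R 4.3.3 on the log2 values as deposited, without any filter on dim probe sets and without the 115 control probe sets. A linear model with 1 mean for each of the 6 groups was fitted to all 18 arrays (12 residual degrees of freedom), followed by eBayes with an intensity trend (8.06 prior degrees of freedom). Two-sided moderated tests were adjusted by the Benjamini-Hochberg method within each comparison over 15502 probe sets, with a threshold of 0.05 on the adjusted p. The comparisons were anti-mir-34 LNA against mock LNA at each age, the F-test of any of these 3 effects, the F-test of the injection-by-age interaction, and mock LNA arrays at 7 against 1 hpf and at 24 against 7 hpf. Each log2 difference is given with limma's standard error (SE), and group levels with the SD over 3 arrays. Adjusted p-values of probe sets are limma's throughout. For a single value, 3 arrays against 3 cannot give an exact permutation p below 0.1.

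Gene lists were tested with limma's camera, which asks whether the genes of a list rank higher or lower than the other genes, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 22 lists within a comparison. The lists cover maternal and germ line transcripts, gastrula patterning, neural progenitors, neurons, glia, Notch signalling, genes reported as miR-34 targets, the cell cycle, p53 and apoptosis, stress, innate immunity, cilia, muscle, heart, blood, endothelium, epidermis, crest and skeleton, eye, yolk and liver, ribosomal proteins, and loading controls. Of the 37 miR-34 target genes on the array, 18 are also in another list, as are 12 of 28 Notch genes, 7 of 45 gastrula genes and 1 of 26 maternal genes. A list's median, mean and test differed in sign for 7 lists at 1 hpf, 2 at 7 hpf and 10 at 24 hpf in the LNA comparisons, and for 5 and 1 lists in the 2 age comparisons, none of them among the lists past the threshold. The adjusted p with a correlation estimated from these arrays is printed for each list that passed. A higher adjusted p in this version is not by itself a sign of correlated genes. The p53 list's estimated correlation was 0.00756, below 0.01, yet its adjusted p between mock embryos of 1 and 7 hpf went from 0.0263 to 0.163 in camera. The test fry, which asks whether a list's genes move one way on balance without comparing them with other genes, was run as a further description and is not reported by value.

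The groups, the models, the lists, the alternatives and the rule for named genes were fixed before the data were examined. For each LNA comparison, the rule names the 10 genes with the largest rise and the 10 with the largest fall among probe sets with 1 symbol that is no clone name, past the threshold and with all 3 arrays of one group on one side of the other 3. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not past it. Up to 4 members of each list are added, or 3 members and 5 genes per direction in the age comparisons. Genes chosen after their values were seen are said to be so. The alternatives fixed in advance were quantile normalization, median centring, leaving out the 1 in 3 probe sets with the lowest means, a variance prior without a trend, the 6 arrays of an age alone, the replicate number as a block, an estimated correlation for lists, and leaving out each array in turn. Damping of low values, lists with an array left out, and the block together with an estimated correlation were added after the data had been seen. Whether other splits of the same arrays gave as many calls was counted for each comparison.

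The fit was tested on simulated data drawn from each real probe set's mean at each age and its residual spread, with 12 simulations and 100 probe sets per simulation changed by each of 2 sizes among 15502. At 1 hpf, 8.42% of changes of 1 and 45.4% of changes of 2 on the log2 scale were recovered, and 5.28% of calls were false. At 7 hpf these shares were 7.92%, 47.9% and 4.56%, and at 24 hpf 8.17%, 46.7% and 7.06%. The recovered share of changes of 2 ranged from 29% to 56% between simulations at 1 hpf, and the mean estimated change was 1.008, 0.984 and 1.011 of the true change of 1 at the 3 ages. A simulated list of 40 genes shifted by 0.5 at 7 hpf was called by camera in 12 of 12 simulations, and 0 of 252 unshifted lists were. The simulated noise was independent between probe sets and had the same spread in all 6 groups. False calls among correlated genes were therefore not tested. In the real arrays the estimated correlation was 0.22 for the gastrula list, 0.282 for the maternal list and 0.364 for ribosomal proteins. The first version of this test used 1 simulation and a tolerance of 10% on the estimated change; after that run missed the tolerance at 1 hpf, 12 simulations were pooled and the tolerance became 3 SE. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

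The planned search for miR-34 and miR-430 seed matches in 3' untranslated regions was not run, since no genome or transcript sequences were used here. The mir-34 genes are not analysed here, so nothing in these values checks how far mir-34 was knocked down.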

Results

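Gene expression was measured in whole zebrafish embryos that had been injected with an LNA oligonucleotide against mir-34 or with a mock LNA and collected at 1, 7 or 24 hpf, with 3 arrays in each of 6 groups. The labels describe the RNA of 1 hpf as maternal, that of 7 hpf as the change from maternal to zygotic transcripts and that of 24 hpf as zygotic. Age set the main differences between the arrays: the first principal component held 56.5% of the variance, the next 16.2% and the one after that 3.28%. Within groups, the mean correlation of an array with the other 2 lay between 0.89 and 0.94. The median level of 26 maternal and germ line genes was 8.26 ± 0.06 (SD, n = 3) in mock embryos of 1 hpf, 6.67 ± 0.56 at 7 hpf and 2.17 ± 1.80 at 24 hpf. One array stood apart in that last group: mock replicate 2 of 24 hpf had a maternal median of 4.21, against 1.52 and 0.79 in the other 2. At 7 hpf the mock arrays differed among themselves, with medians of 45 gastrula patterning genes of 5.61, 4.38 and 6.29. The difference between the 3' and 5' probe sets of GAPDH is a sign of RNA integrity and labelling. In mock embryos it was -0.17 ± 0.32 at 1 hpf, -0.12 ± 0.75 at 7 hpf and between 0.99 and 1.72 on the 3 arrays of 24 hpf. In anti-mir-34 embryos it was -0.04 ± 0.23, -0.03 ± 1.19 and 1.51 ± 0.28 at the 3 ages.

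**Figure D1:**
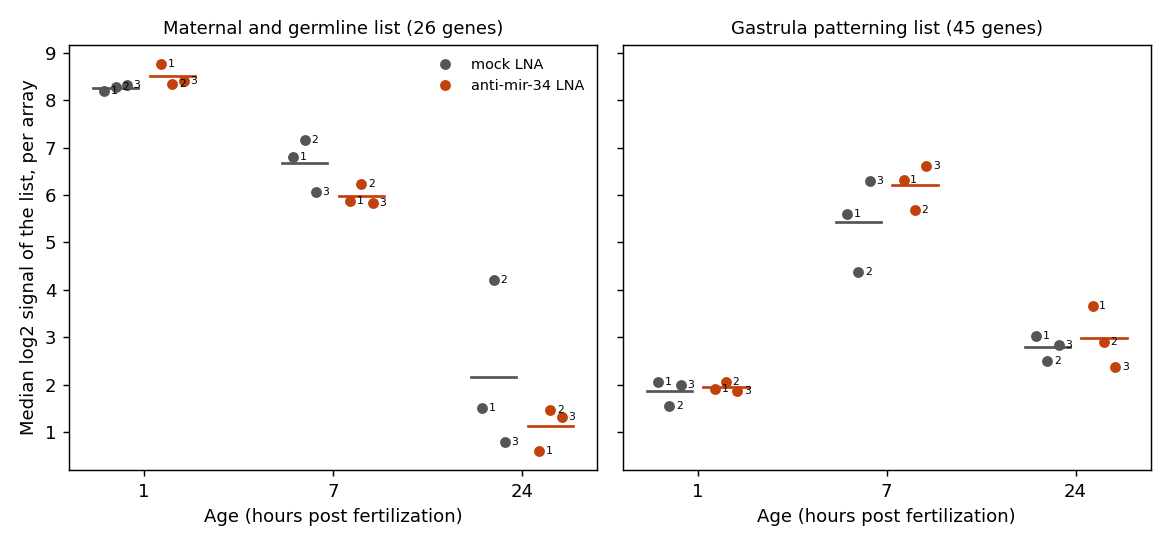
Median log2 signal of the maternal and germ line genes and of the gastrula patterning genes on each of the 18 arrays, by age (horizontal axis, hpf) and injection, with 1 point per array and a short line at each group mean. Mock replicate 2 of 24 hpf lies at 4.21 for the maternal genes, above 1.52 and 0.79 in the other mock arrays of that age.

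The course of development without knockdown was read from mock embryos, first between 1 and 7 hpf. Keratins of the outer cell layer rose: krt18a.1 rose by 10.40 ± 0.61 (SE, n = 3 per age), krt4 by 8.41 ± 0.32, krt5 by 8.88 ± 0.47 and krt97 by 8.91 ± 0.38 on the log2 scale. Their adjusted p ranged from 4.44e-13 to 1.85e-10. All 4 started from levels below 2, where signal and background are not told apart, so the sizes are not exact. With 16 added to the signals before the logarithm they rose by 5.94, 6.03, 5.56 and 5.20. The epithelial gene lye rose by 9.33 ± 0.50 (5.62 with 16 added), and wdr90, which codes for a WD-repeat protein, rose from 0.99 to 10.99 (adjusted p = 2.99e-11; 6.81 with 16 added). The oocyte growth factor bmp15 fell by 4.24 ± 0.66 (8.91 to 4.67, adjusted p = 6.65e-05), while its second probe set differed by -1.16 (adjusted p = 0.248). The lipase gene lipg fell by 4.40 ± 0.49 and fhdc3 by 4.60 ± 0.49. Lower on the scale, nmrk2 fell by 4.34 ± 0.79 and kcnh6a by 3.87 ± 1.37 (adjusted p = 0.0449). With 16 added their differences were only -0.24 and -0.63. The call of kcnh6a was lost without mock 1 hpf replicate 1 or 2 or mock 7 hpf replicate 1 or 3 (adjusted p = 0.205, 0.054, 0.138 and 0.133), and with 16 added to the signals (0.155). In all, 3722 of 15502 probe sets passed, of which 2103 rose and 1619 fell. The balance turned with 16 added to the signals, to 1968 up and 2309 down. In 40.3% of probe sets the 3 arrays of one age lay on one side of the other 3, where chance gives 10%. The median difference over all genes was -0.22.

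Germ layer and axis genes rose together between 1 and 7 hpf. Of 45 gastrula patterning genes 35 rose and 1 fell (37 and 1 adjusted over the list alone), with a median of 3.35. Among them were tbxta, the T-box factor of the notochord (6.25 ± 0.65), foxa2 of axial mesoderm and endoderm (5.19 ± 0.50) and the ventral repressor vox (5.06 ± 0.51). All 69 ribosomal protein genes had positive differences, with a median of 0.97, and 54 of them passed (60 adjusted over the list alone). For example, rps16 rose by 1.78 ± 0.20 and rpl36a by 1.95 ± 0.25. Of 40 epidermal genes 19 rose and 2 fell (20 and 2 adjusted over the list alone). Of 38 yolk and liver genes 15 rose and 4 fell (17 and 4 adjusted over the list alone), among them the apolipoproteins apoeb (8.66 ± 0.41) and apoc1 (7.22 ± 0.49). These 4 lists ranked above other genes in camera with adjusted p = 7.69e-19, 7.69e-19, 9.65e-09 and 0.00243 in the order given. None held with an estimated correlation: adjusted p = 0.0617, 0.164, 0.0617 and 0.295 with an estimated correlation.

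Neural progenitor genes also ranked higher at 7 than at 1 hpf in camera (adjusted p = 0.00639; adjusted p = 0.215 with an estimated correlation). Of 50 genes 17 rose and 1 fell (17 and 2 adjusted over the list alone). Of these, sox19a rose by 6.21 ± 0.54 and sox11a by 4.76 ± 0.37. Of 28 Notch pathway genes 10 rose and 2 fell (10 and 3 adjusted over the list alone), among them the hairy-related factors hes6 (3.90 ± 0.37) and her9 (4.96 ± 0.67). Of 37 genes reported as miR-34 targets 12 rose and 6 fell, with the same numbers adjusted over the list alone. The cyclin gene ccnd1 rose by 7.05 ± 0.52 and sox2 by 3.58 ± 0.40, while a dim probe set of sox2 differed by -0.61. Of 33 p53 and apoptosis genes 10 rose and 3 fell (11 and 4 adjusted over the list alone), with sesn3 at 5.66 ± 0.37 and tp53inp1 at 2.88 ± 0.23. Adjusted p in camera was 0.0109, 0.032 and 0.0263 for these last 3 lists. None held here either, at adjusted p = 0.261, 0.295 and 0.163 with an estimated correlation. For the p53 list that correlation was 0.00756, below the 0.01 of the main test.

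Maternal and germ line genes ranked lower at 7 than at 1 hpf, with a median of -1.36 (adjusted p = 0.0263; adjusted p = 0.512 with an estimated correlation). Of 26 genes 7 fell and 1 rose, also when adjusted over the list alone. The egg coat gene zp3b fell by 2.11 ± 0.41, and the RNA-binding protein gene ybx1 rose by 1.94 ± 0.28, with -0.81 for a dim second probe set. Of 47 cell cycle genes 18 fell and 4 rose (19 and 6 adjusted over the list alone). The mitotic checkpoint gene mad2l1 fell by 2.19 ± 0.20, and the replication gene mcm3 rose by 5.65 ± 0.57, with 1.44 for a second probe set that did not pass. The list's adjusted p was 0.0421, and adjusted p = 0.335 with an estimated correlation. Of 43 stress genes 11 rose and 4 fell (12 and 4 adjusted over the list alone; adjusted p = 0.0247; adjusted p = 0.164 with an estimated correlation). The small heat shock protein gene hspb1 rose by 6.42 ± 0.32 and the immediate early gene jun by 6.50 ± 0.43. Of 16 loading control genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0263; adjusted p = 0.25 with an estimated correlation), among them actb1 (1.51 ± 0.25).

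Single arrays ended some of these list calls. Without mock 1 hpf replicate 3 or mock 7 hpf replicate 3, adjusted p of the maternal list was 0.0639 or 0.0742. Without mock 1 hpf replicate 1 or 3 or mock 7 hpf replicate 2, that of the cell cycle list was 0.0884, 0.0837 or 0.123. Without mock 1 hpf replicate 2 or mock 7 hpf replicate 2, that of the controls was 0.0758 or 0.0612. Without mock 7 hpf replicate 3, that of the miR-34 targets was 0.0677 and that of the p53 list 0.0549. The other 10 lists did not pass between 1 and 7 hpf, with adjusted p from 0.275 for the eye to 0.719 for the endothelium. Single members passed in each of them. The blood and ectoderm factor gata2a rose by 6.52 ± 0.57, the actin-bundling gene lcp1 of leukocytes by 8.03 ± 0.67 and the ubiquitin-like isg15 by 4.60 ± 0.46. The neural crest gene crestin rose by 4.92 ± 0.49, the heart and endoderm factor gata5 by 4.44 ± 0.68 and the muscle factor myf5 by 4.61 ± 0.78. With 16 added to the signals these 3 rose by 0.86, 2.19 and 0.87.

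The numbers of genes that rose and fell in these 10 lists were 4 and 1 of 27 for blood, 3 and 5 of 34 for cilia, 7 and 3 of 41 for crest and skeleton, 1 and 2 of 15 for the endothelium, and 3 and 0 of 24 for the eye. They were 3 and 1 of 14 for glia, 4 and 1 of 16 for the heart, 5 and 2 of 26 for innate immunity, 5 and 3 of 46 for muscle and 3 and 6 of 53 for neurons. Adjusted over the list alone, they were 3 and 2 for glia, 5 and 1 for the heart, 5 and 2 for muscle and 1 and 1 for neurons, and the same as above for the other 6.

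Between 7 and 24 hpf, genes of differentiated muscle rose from near the bottom of the scale to its top in mock embryos. The fast myosin genes myhz1.3 and myl1 rose by 11.94 ± 0.84 (SE; -1.71 to 10.23, n = 3 per age) and 11.06 ± 0.70. The parvalbumin gene pvalb2 rose by 10.84 ± 0.43, and atp2a1, the calcium pump of the sarcoplasmic reticulum, by 10.04 ± 0.44. Adjusted p of these 4 ranged from 6.18e-13 to 1.42e-09. The levels at 7 hpf are not told apart from background, so these sizes are not exact either, and with 16 added to the signals they were 6.21, 5.98, 6.14 and 6.25. The collagen gene col2a1a of notochord and cartilage rose by 10.43 ± 0.80 (5.54 with 16 added). Oocyte transcripts fell: ccna1 by 8.64 ± 0.90, the oocyte linker histone h1m by 8.41 ± 1.01, the egg coat genes zp2.6 by 8.32 ± 0.66 and zp3d.1 by 7.78 ± 0.74, and the oocyte kinase wee2 by 7.93 ± 0.83. At 24 hpf h1m stood at 5.62 in mock replicate 2 and at -0.68 and -0.36 in the other 2 mock arrays. In all, 6662 probe sets passed, of which 3026 rose and 3636 fell. The arrays of the 2 ages did not overlap in 52.3% of probe sets, where chance gives 10%, and the median over all genes was -0.20. The 3' to 5' difference of GAPDH moved with this age step, from -0.12 ± 0.75 to between 0.99 and 1.72.

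**Figure D2:**
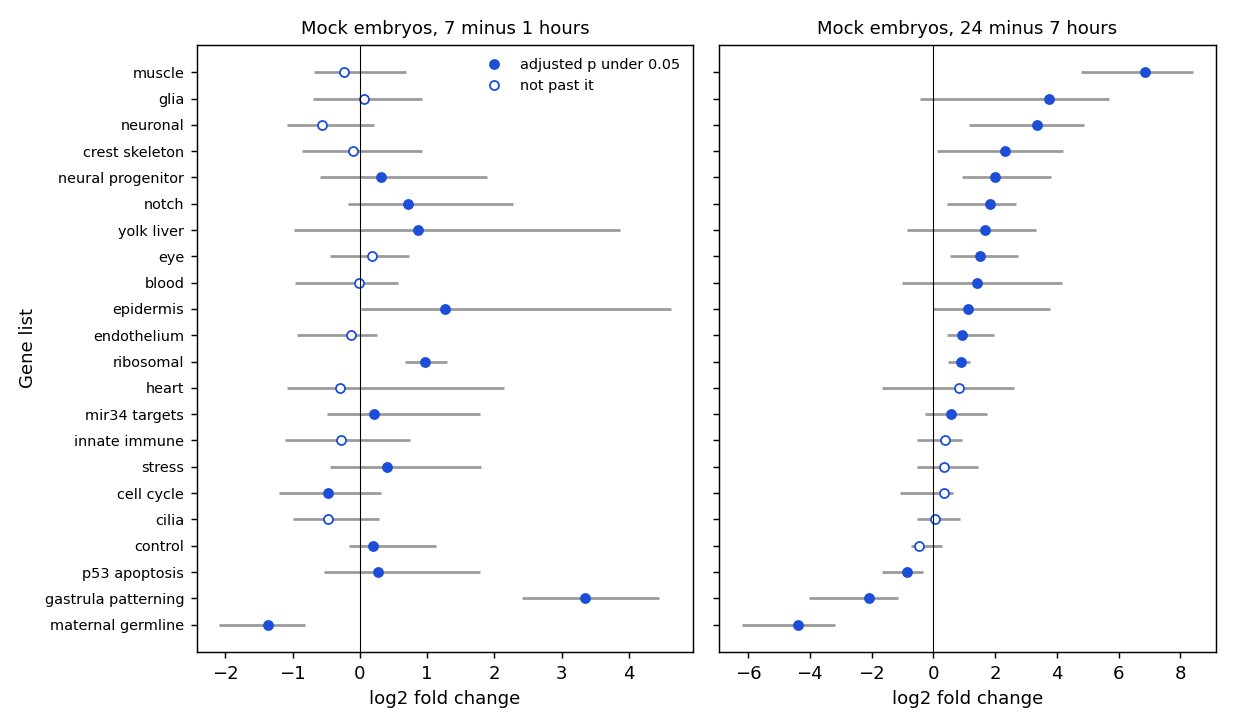
Median log2 difference (points) and quartiles (bars) of the genes of each of the 22 lists between mock embryos of 1 and 7 hpf and of 7 and 24 hpf, with filled points where camera's adjusted p was below 0.05. Muscle genes have a median of 6.87 between 7 and 24 hpf, and maternal and germ line genes one of -4.38.

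Of 46 muscle genes 40 rose and 0 fell between 7 and 24 hpf (41 and 1 adjusted over the list alone), with a median of 6.87. The actin gene actc1b rose by 8.47 ± 0.27, with -1.19 and -0.43 for 2 dim probe sets. Of 53 neuronal genes 36 rose and 1 fell (37 and 2 adjusted over the list alone), among them the thymosin gene tmsb (7.85 ± 0.51) and the reticulon gene rtn1a (4.89 ± 0.38). Neural progenitor genes followed with 32 of 50 up and 2 down (32 and 3 adjusted over the list alone), among them the proneural factors ascl1a (5.37 ± 0.36) and neurog1 (4.32 ± 0.41). Of 41 crest and skeleton genes 25 rose and 2 fell, and of 24 eye genes 11 rose and 2 fell, each with the same numbers adjusted over the list alone. Of 14 glial genes 7 rose and 2 fell (8 and 2 adjusted over the list alone). In these 3 lists the pigment cell genes gch2 (9.29 ± 0.58) and dct (4.84 ± 0.31), the lens crystallin gene crybb1 (7.00 ± 0.63) and the glutamate transporter slc1a2b (4.80 ± 0.35) rose. Of 33 p53 and apoptosis genes 14 fell and 0 rose, also when adjusted over the list alone, for example gadd45bb, which fell by 5.12 ± 0.73, and bcl2l10, which fell by 2.47 ± 0.27.

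These 7 lists passed camera with adjusted p = 1.14e-27 for muscle, 9.64e-14 for neurons, 3.53e-09 for neural progenitors, 6.02e-07 for crest and skeleton, 0.00211 for the eye, 0.00587 for glia and 0.00836 for p53 and apoptosis. They passed with an estimated correlation too. Adjusted p was then 6.91e-07 for muscle, 0.000182 for neurons, 0.0087 for neural progenitors, 0.0024 for crest and skeleton, 0.0151 for the eye and 0.0488 for both glia and p53.

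Maternal and germ line genes ranked lower at 24 than at 7 hpf in camera (adjusted p = 4.11e-08; adjusted p = 0.0854 with an estimated correlation). Of 26 genes 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -4.38. The germ cell helicase gene ddx4 fell by 6.12 ± 0.44 and zar1 by 4.26 ± 0.43. Of 45 gastrula patterning genes 29 fell and 1 rose (31 and 1 adjusted over the list alone), such as the Nodal inhibitor lft2, which fell by 5.76 ± 0.63, and vox, which fell by 4.63 ± 0.51. The gastrula list had adjusted p = 1.95e-05, and adjusted p = 0.192 with an estimated correlation. Of 69 ribosomal protein genes 50 rose (52 adjusted over the list alone), for example rpl5a by 1.75 ± 0.24. Of 28 Notch genes 14 rose and 2 fell, and of 40 epidermal genes 16 rose and 4 fell, each with the same numbers adjusted over the list alone. The Delta ligand gene dlb rose by 5.72 ± 0.64 and col1a2 by 9.52 ± 0.57. Adjusted p of these 3 lists was 3.27e-10, 7.93e-05 and 0.000139, and adjusted p = 0.192, 0.0618 and 0.0719 with an estimated correlation.

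Globin genes rose between 7 and 24 hpf, hbbe3 by 9.86 ± 0.53 and hbae3 by 8.13 ± 0.55. Of the 27 genes of the blood list 13 rose and 6 fell (14 and 6 adjusted over the list alone; adjusted p = 0.00157; adjusted p = 0.123 with an estimated correlation). Of 15 endothelial genes 5 rose, also when adjusted over the list alone, among them the receptor gene kdrl by 5.27 ± 0.87. The list's adjusted p was 0.0103, and adjusted p = 0.0618 with an estimated correlation. Of 38 yolk and liver genes 19 rose and 9 fell (20 and 9 adjusted over the list alone; adjusted p = 0.0173; adjusted p = 0.352 with an estimated correlation). Of 37 miR-34 target genes 13 rose and 7 fell (15 and 7 adjusted over the list alone; adjusted p = 0.0269; adjusted p = 0.204 with an estimated correlation). Of these, the pluripotency factor nanog fell by 6.65 ± 0.62 and myca rose by 3.85 ± 0.47. Without mock 7 hpf replicate 2, adjusted p was 0.0548 for yolk and liver and 0.0734 for the miR-34 targets.

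The other 6 lists did not pass between 7 and 24 hpf, with adjusted p from 0.126 for heart and stress to 0.909 for the cell cycle. Their numbers of genes that rose and fell were 7 and 3 of 16 for the heart, 13 and 7 of 43 for stress, 4 and 2 of 26 for innate immunity, 5 and 1 of 34 for cilia, 4 and 5 of 16 for the controls and 11 and 16 of 47 for the cell cycle. Adjusted over the list alone, they were 7 and 3, 15 and 7, 3 and 2, 5 and 1, 4 and 5, and 11 and 17. The cell cycle list had a median of 0.33 and a mean of -0.28, and of its members ccne1 fell by 4.15 ± 0.44 and ccnb2 by 3.26 ± 0.32. The heart myosin gene myl7 rose by 6.56 ± 0.76.

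At 1 hpf, soon after the injection, 191 probe sets of 148 genes differed between anti-mir-34 and mock embryos. The cap-binding gene eif4e3 was higher by 2.46 ± 0.33 (SE, n = 3 per group; 7.68 ± 0.23 against 5.22 ± 0.57, SD; limma adjusted p = 0.00096), with 1.66 for a second probe set that did not pass (0.21). The gene tardbpb, which codes for the RNA-binding protein TDP-43, was higher by 1.73 ± 0.26 (7.87 against 6.14, adjusted p = 0.00236). Lower were malsu1, a factor of mitochondrial ribosome assembly (-3.05 ± 0.35; 0.55 against 3.60, adjusted p = 0.000251), and alas1, which codes for the first enzyme of heme synthesis (-2.53 ± 0.36, adjusted p = 0.0014). For eif4e3, tardbpb and malsu1, the call held with any of the 6 arrays left out. With 16 added to the signals, the differences of eif4e3 and tardbpb were 2.04 and 1.52 (adjusted p = 0.000802 and 0.00251), and that of malsu1 was -0.68 and did not pass (0.0616). The smallest p belonged to the nucleolar helicase gene ddx21, which was chosen after its values were seen (-1.97 ± 0.21; 6.18 ± 0.16 against 8.15 ± 0.23, adjusted p = 0.000151).

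**Figure D3:**
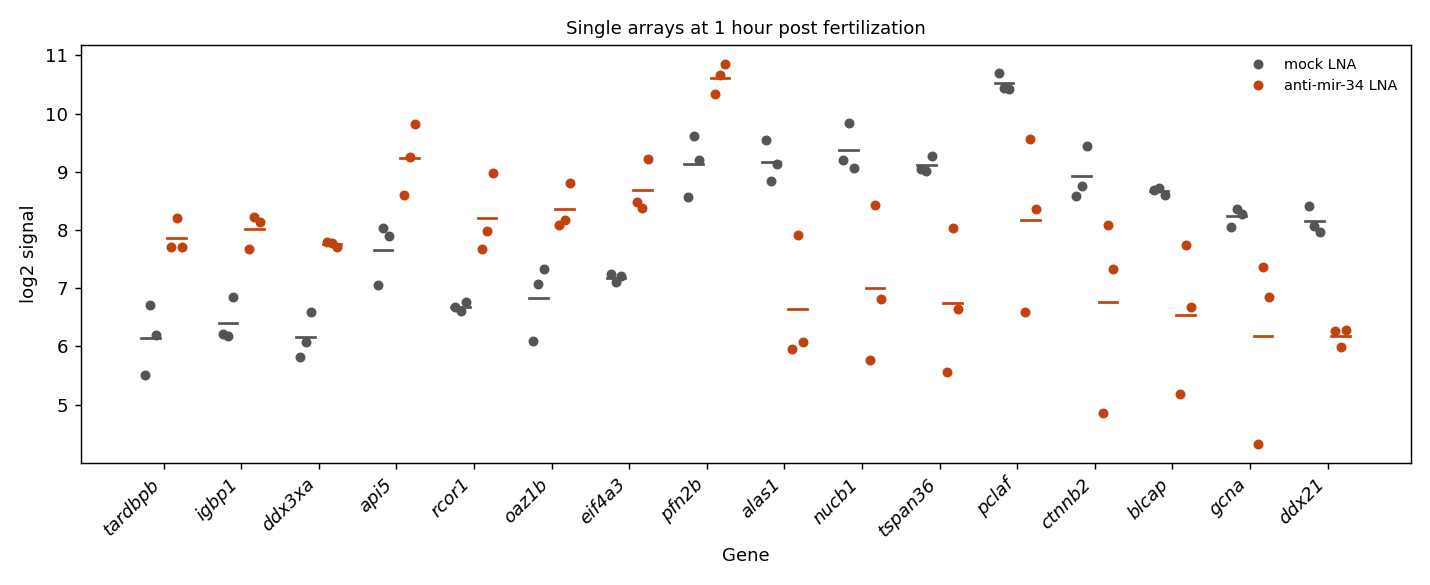
Log2 signal at 1 hpf of 16 genes, chosen after the values were seen as bright genes past the threshold, on each of 3 mock and 3 anti-mir-34 arrays (points) with group means (short lines). The 8 genes on the higher side differ by 1.49 to 1.73, and the 8 on the lower side by -2.53 to -1.97.

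Of the 191 probe sets 66 were higher and 125 lower after anti-mir-34 injection, 186 of them by more than 2-fold. At unadjusted p below 0.05 there were 1524 probe sets where chance gives 775. The arrays of the 2 groups did not overlap in 12.7% of probe sets, where chance gives 10%. Bright genes on the higher side, chosen after their values were seen, were also igbp1 (1.60), the RNA helicase ddx3xa (1.60), api5 (1.57), rcor1 (1.53), oaz1b (1.53), eif4a3 (1.51) and the profilin gene pfn2b (1.49). Further probe sets of igbp1, ddx3xa, api5, rcor1 and oaz1b did not pass, and that of api5 differed by -0.12. On the lower side were nucb1 (-2.37), tspan36 (-2.37) and the PCNA-binding factor pclaf (-2.35), and, chosen after their values were seen, the beta-catenin gene ctnnb2 (-2.17), blcap (-2.14) and gcna (-2.06). One of 3 other probe sets of nucb1 differed by 0.10, and none of the 3 passed. The anti-mir-34 arrays were not alike in the lower genes: pclaf stood at 6.59, 9.57 and 8.36 on these 3 arrays and between 10.43 and 10.70 on the mock arrays. Over the 125 lower probe sets the median SD was 0.78 in anti-mir-34 and 0.28 in mock embryos, and over the 66 higher ones 0.36 and 0.40. The model took 1 spread per probe set for all 6 groups, so limma's SE and p can be too small for the lower probe sets.

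The other genes with the largest differences at 1 hpf under the naming rule lay mostly near the bottom of the scale. Higher were pck2, a mitochondrial enzyme of gluconeogenesis (3.40 ± 0.60; 2.38 against -1.02, adjusted p = 0.00597), krt97 (2.13 ± 0.38, adjusted p = 0.00597), the muscle gene mybpc2b (2.43), gbgt1l4 (2.28), grnas (2.16), the homeobox gene hhex (2.09), dna2 (1.65) and cavin2a (1.63). Lower were the transcription factor ebf2 (-3.74 ± 0.60; -1.61 against 2.13, adjusted p = 0.00363), tsc22d3 (-3.20 ± 0.54, adjusted p = 0.00511), chka (-3.35) and the forkhead gene foxa1 (-2.49). Brighter was cab39l (-3.24 ± 0.63; 5.01 ± 2.27 against 8.25 ± 0.14), of which 2 other probe sets did not pass (-1.68 and -1.15). With 16 added to the signals, gbgt1l4, dna2 and cab39l passed (adjusted p = 0.0133, 0.0141 and 0.00278), while the other 10 had differences between -0.37 and 0.45 and adjusted p of 0.397 to 0.958. Of all these, mybpc2b, gbgt1l4, grnas, hhex, dna2, cavin2a, chka and foxa1, and bcl2l10 of the apoptosis list, lost their call without some array. Leaving out mock replicate 1, 2 or 3 ended 8, 6 and 4 of these 9 calls, with adjusted p of 0.0506 to 0.21, 0.0514 to 0.149 and 0.0611 to 0.165. Leaving out anti-mir-34 replicate 1, 2 or 3 ended 7, 2 and 5, with adjusted p of 0.0833 to 0.196, 0.0536 to 0.0788 and 0.054 to 0.185. A probe set of ppp1r3ca differed more than ebf2 (-3.82 ± 0.66, adjusted p = 0.00567) but did not meet the naming rule.

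No gene list passed between the injections at 1 hpf: camera gave adjusted p = 0.901 for each of the 22 lists, and 0.962 with an estimated correlation. Over all probe sets, 5 list members passed. The mitotic kinase gene cdk1 was lower (-1.58 ± 0.25; 5.56 against 7.14, adjusted p = 0.00302), as was the cell death inhibitor bcl2l10 (-1.26 ± 0.27, adjusted p = 0.0212). Higher were hhex, mybpc2b and the translation factor gene eif4a1a of the control list (7.67 against 6.37, adjusted p = 0.00236), of which a second probe set differed by 0.51 without passing. Of the 37 miR-34 target genes 0 passed limma's test over all probe sets and 2 were lower when adjusted over the list alone, with a median of -0.02. Adjusted over the list alone, 1 gene was higher and 1 lower in the blood list, 2 higher and 1 lower in the heart list, 2 higher in the controls, 1 higher in each of the gastrula and muscle lists, 1 lower in the cell cycle list and 2 lower in the p53 list. In the other 14 lists the number was 0. The p53 list had a median of 0.16 with mdm2 at 0.94 (adjusted p = 0.162) and mdm4 at -0.95 (adjusted p = 0.112). Without mock replicate 1 the count of 191 was 89, of which 75 were shared, and without anti-mir-34 replicate 2 it was 468. Without an intensity trend in the variance prior it was 58, and with the 6 arrays of that age alone limma called 0, with 1145 at unadjusted p below 0.05. With the replicate number as a block the count was 390.

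At 7 hpf, gastrula patterning genes ranked higher and maternal genes lower in anti-mir-34 than in mock embryos in camera. Neither ranking held, at adjusted p = 0.406 and 0.444 with an estimated correlation. Of 45 gastrula genes 42 had a positive difference, with a median of 0.82, for example the BMP antagonist chrd (1.16 ± 0.49; 6.96 ± 0.35 against 5.80 ± 1.04, SD, n = 3 per group) and foxa2 (0.91 ± 0.50). Of 26 maternal genes 2 had a positive difference, with a median of -0.88, for example the germ cell gene dazl at -1.79 ± 0.46 and the Piwi gene piwil2 at -1.90 ± 0.63. Notch genes also ranked higher (median 0.72; adjusted p = 0.406 with an estimated correlation; her6 at 1.15 ± 0.36), as did ribosomal protein genes (0.21; rpl27 at 0.77 ± 0.27), epidermal genes (0.65; icn at 1.47 ± 0.28), crest and skeleton genes (0.51; matn1 at 1.35 ± 0.49, but dlx6a at -1.60 ± 0.46) and yolk and liver genes (0.55; apoa1a at 1.09 ± 0.62). The rankings of these last 4 lists did not hold either, at adjusted p = 0.406 for epidermal and crest genes and 0.444 for the other 2 with an estimated correlation. Of the 4 crest and skeleton genes with the largest t in size, dlx6a, sox9b (-1.22) and tfap2b (-2.16) were lower and matn1 higher. Of the 4 such epidermal genes, epcam was lower (-0.90, with 1.40 for another probe set). The others, icn, icn2 (-0.21 for another probe set) and col1a2, were higher. Of the 4 such yolk and liver genes, fabp3 was lower (-0.87) and serpina1l, ambp and apoa1a higher. None of the single genes named here passed, with adjusted p from 0.0803 for icn to 0.481 for apoa1a.

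Camera's adjusted p at 7 hpf was 1.48e-05 for the gastrula list, 0.00035 for ribosomal proteins, 0.0022 for Notch, 0.00226 for the maternal and the epidermal list, 0.0491 for yolk and liver and 0.0493 for crest and skeleton. None of the 7 held with an estimated correlation, at 0.406 or 0.444. Over all probe sets limma called 0 members of any of the 22 lists. Adjusted over the list alone, 2 maternal genes fell and 1 epidermal gene rose, and 0 members of the gastrula, Notch, ribosomal, crest and yolk and liver lists passed. Of the 37 miR-34 targets 1 rose and 3 fell adjusted over the list alone. That list had a median of 0.37, with 26 of 37 genes positive (adjusted p = 0.0817; 0.444 with an estimated correlation). The other 14 lists had adjusted p from 0.111 to 0.985. Adjusted over the list alone, 3 stress genes rose and 1 fell, 1 heart gene rose, 1 neuronal gene and 1 control gene fell, and 0 passed in the remaining 10.

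Single arrays decided most of these calls. Without mock 7 hpf replicate 2, the array with the lowest gastrula median, the maternal list was the only one to pass. Adjusted p was then 0.0917 for gastrula and Notch genes, 0.0992 for crest, 0.13 for ribosomal, 0.218 for epidermal and 0.319 for yolk and liver genes. Yolk and liver and crest genes did not pass either without mock replicate 1 (0.0688 for both), anti-mir-34 replicate 2 (0.0895 for both) or anti-mir-34 replicate 3 (0.209 and 0.175). Without mock replicate 3, the miR-34 targets and neural progenitors (both 0.0346) and p53 genes (0.0384) passed as well.

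Single genes passed in 2 cases at 7 hpf, both lower after anti-mir-34 injection with all 3 arrays below the 3 mock arrays. The ring finger gene rnf175 differed by -2.98 ± 0.46 (1.57 ± 0.64 against 4.55 ± 1.31) and the Polycomb gene bmi1b by -2.21 ± 0.36 (3.81 ± 0.53 against 6.01 ± 0.76), both with adjusted p = 0.0347. With 16 added to the signals rnf175 differed by -1.14 (adjusted p = 0.0607) and bmi1b by -1.43 (0.037). At unadjusted p below 0.05 there were 1926 probe sets where chance gives 775. The groups did not overlap in 15.5% of probe sets, where chance gives 10%. Not past the threshold on the higher side were the cartilage matrix gene matn4, icn, actn2b (2.26 ± 0.47), the laminin gene lama5 (2.52 ± 0.61) and eif4enif1 (1.31 ± 0.34). On the lower side were mid1ip1l (-2.14 ± 0.39), zdhhc4 (-1.35 ± 0.25) and the zinc transporter gene slc30a9 (-1.76 ± 0.34; -0.15 and -0.14 for 2 other probe sets), each with adjusted p = 0.0803. These 3 passed with 16 added to the signals (0.0277, 0.0277 and 0.0475). They were followed by cax1 (-1.71 ± 0.34) and tmx2a (-2.18 ± 0.44, with 0.48 for its other probe set). For matn4 (0.81 against -3.02, adjusted p = 0.0627) 2 of the 3 mock arrays stood at the lowest deposited value, so its difference has no exact size, and with 16 added to the signals it was 0.14 (adjusted p = 0.825).

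The count of 2 at 7 hpf was unstable. Limma called 0 without mock replicate 1 or 2 or anti-mir-34 replicate 1 or 3, with 1525, 786, 1331 and 1191 at unadjusted p below 0.05. Adjusted p of both rnf175 and bmi1b was then 0.187, 0.209, 0.154 and 0.173. Limma called 403 without mock replicate 3 and 77 without anti-mir-34 replicate 2. It called 0 without the intensity trend (1755 at unadjusted p below 0.05) and with the 6 arrays of 7 hpf alone (1671). It called 22 or 28 when 16 or 4 was added to the signals before the logarithm. With the replicate number as a block it called 219, of which 26 were higher and 193 lower.

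At 24 hpf, maternal and germ line transcripts ranked lower in anti-mir-34 than in mock embryos, with a median of -0.64, and this rested on 1 mock array. Camera gave the list an adjusted p = 5.25e-05, and an adjusted p = 0.99 with an estimated correlation. The germ plasm organizer buc stood at -1.59 ± 1.08 against 1.87 ± 2.21 (SD, n = 3 per group), a difference of -3.46 ± 0.75 (SE, limma adjusted p = 0.427). In buc mock replicates 1 and 2 were both high, at 2.48 and 3.71 against -0.58 in replicate 3, without which the gene passed (-4.68, adjusted p = 0.00322). The differences of mos, gdf3 and bmp15 were -2.28 ± 0.73, -2.34 ± 0.77 and -1.95 ± 0.66, and none passed. Of the 26 genes 0 passed limma's test over all probe sets, and 1 fell adjusted over the list alone. In mock replicate 2 gdf3 stood at 5.49, against 1.99 and 0.74 in the other mock arrays. Without this array the list had a median of -0.12 and adjusted p = 0.8. The other 21 lists had adjusted p from 0.634 to 0.99, with 0 members past the threshold over all probe sets or adjusted over the list alone. The miR-34 targets had a median of 0.02 with adjusted p = 0.99. The yolk and liver list (median -0.12) passed without mock replicate 2 or anti-mir-34 replicate 1, at adjusted p = 0.0306 and 0.00195.

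Limma called 2 probe sets at 24 hpf, 1 of them with a single gene symbol, chosen here after its values were seen. This probe set of cdpf1 was higher by 2.79 ± 0.44 (2.64 against -0.16, adjusted p = 0.0314), while the brightest probe set of the gene differed by 0.00 and a further one by 0.86, both with adjusted p = 0.999. Among genes not past the threshold, gemin5 (1.34 ± 0.30, with -1.29 for another probe set), the lactate dehydrogenase gene ldhd (2.46 ± 0.58), fars2 (2.17 ± 0.52, with -0.75 for another probe set), ciz1b (2.42 ± 0.58) and mios (1.09 ± 0.28) were on the higher side. On the lower side were gtf3ab (-2.82 ± 0.66), larp6b (-2.50 ± 0.60), ghdc (-1.66 ± 0.42) and eif4e1b (-1.35 ± 0.36). Adjusted p of these 9 ranged from 0.486 to 0.75. At unadjusted p below 0.05 there were 686 probe sets where chance gives 775, and the groups did not overlap in 9.17% of probe sets, where chance gives 10%. Limma called 0 without anti-mir-34 replicate 2 or 3 (568 and 632 at unadjusted p below 0.05) and 13 without mock replicate 1. It also called 0 without the intensity trend (739), with the 6 arrays of 24 hpf alone (637) and with 4 added to the signals (600).

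Over the 3 ages together, 44 probe sets of 39 genes differed between the injections at some age, led by ddx21 (adjusted p = 0.00215) and malsu1 (adjusted p = 0.00276). For ddx21 the log2 differences were -1.97 ± 0.21, -0.24 ± 0.21 and -0.20 ± 0.21 (SE) at 1, 7 and 24 hpf, and for malsu1 -3.05 ± 0.35, 0.71 ± 0.35 and -0.15 ± 0.35. The effect differed between ages for 15 probe sets of 12 genes, again with malsu1 and ddx21 (adjusted p of the interaction 0.0104 and 0.035). Between single ages, 42 probe sets had a different effect at 7 than at 1 hpf. Limma called 0 at 24 against 1 hpf and 0 at 24 against 7 hpf, with 1148 and 1333 at unadjusted p below 0.05.

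Both counts, 44 at any age and 15 for the interaction, moved with single arrays. The count of 44 was 5, 8, 19, 229 and 219 without mock 1 hpf replicate 1, mock 1 hpf replicate 3, anti-mir-34 1 hpf replicate 3, anti-mir-34 1 hpf replicate 2 and mock 7 hpf replicate 3. It was 27 without mock 7 hpf replicate 1, 15 and 29 without anti-mir-34 7 hpf replicates 1 and 3, and 29, 23 and 25 without anti-mir-34 24 hpf replicates 1, 2 and 3. The count of 15 was 0, 4 and 2 without mock 1 hpf replicates 1, 2 and 3, where the 0 came with 1568 at unadjusted p below 0.05 in limma. It was 148 without anti-mir-34 1 hpf replicate 2, 1, 3 and 71 without mock 7 hpf replicates 1, 2 and 3, and 1 without anti-mir-34 7 hpf replicate 1 or 3. It was 5, 5 and 1 without mock 24 hpf replicates 1, 2 and 3, and 1 without any of the 3 anti-mir-34 arrays of 24 hpf. With the replicate number as a block the counts were 292 at any age and 111 for the interaction.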

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

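The tests of stage and of miR-34 targets at 7 hpf, of egg RNA and gastrula RNA in mock replicate 2 of 24 hpf, and of the direction of the 1 hpf calls, with its bound of 75%, were chosen after the result was seen; the other tests here were not. The groups hold 3 arrays each, too few for a test of single arrays as outliers.

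The effect of the injection differed between the 3 ages for 15 probe sets. Those with 1 gene symbol were cdpf1 (adjusted p of the interaction 0.0392), eif4e3 (0.0392), eif4a3 (0.0496), igbp1 (0.0463), tiprl (0.0463), ddx21 (0.035), hmg20b (0.0463), cenpe (0.0463), malsu1 (0.0104), ptgr1.1 (0.0392), sumo2b (0.0463) and cdk2ap2 (0.0463). For cdpf1 the differences were 0.52, -1.14 and 2.79 at 1, 7 and 24 hpf. For the other 11 the difference was largest in size at 1 hpf: the kinetochore motor gene cenpe had -1.73, 0.68 and -0.11, the SUMO gene sumo2b -1.67, 0.16 and 0.00, and the chromatin gene hmg20b 1.47, 0.04 and -0.11. Of 100 relabellings of the arrays within ages, 4 gave 15 or more calls, the real one included, a share under 0.05, and the highest of the others gave 101. For a difference at any age, 2 of 100 gave 44 or more, again a share under 0.05, and the highest other gave 178. The median of the other relabellings was 0 for both counts. Relabelling within ages stands for no effect of the injection at any age. The share for the interaction therefore does not itself test whether the effect differs between ages. Relabellings that call several times as many probe sets as the real one may reflect a structure of the samples besides the injection, which was not tested here. The count of 15 was 148 without anti-mir-34 1 hpf replicate 2 and 0 without mock 1 hpf replicate 1 (1568 at unadjusted p below 0.05 in limma).

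Gene lists also had different effects between ages in camera, none of which held, at adjusted p = 0.427 to 0.998 with an estimated correlation. Against 1 hpf, the effect at 7 hpf ranked higher for gastrula genes (adjusted p = 0.00766), Notch genes and ribosomal proteins (both 0.0214) and lower for maternal genes (0.0214). The effect at 24 hpf ranked lower than at 1 hpf for maternal genes (0.0215). At 24 hpf alone, the maternal list had a median of -0.12 and adjusted p = 0.8 in camera without mock replicate 2. The contrast between the ages was not rerun without that array. Against 7 hpf, the effect at 24 hpf ranked lower for gastrula genes (0.000868), Notch genes (0.00163), epidermal genes and ribosomal proteins (both 0.00263) and yolk and liver genes (0.0128).

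At 7 hpf, gastrula genes ranked higher and maternal genes lower in anti-mir-34 embryos in camera, with 0 members past the threshold over all probe sets in limma and adjusted p = 0.406 and 0.444 with an estimated correlation; without mock replicate 2 the gastrula list had adjusted p = 0.0917. Over all probe sets the effect correlated with the change from 1 to 7 hpf (r = 0.46 across genes, which are not independent replicates), and also at r = 0.46 with the main axis of difference among the 3 mock arrays of 7 hpf. Mock arrays lay 34.88, 23.32 and 46.84% of the way from 1 to 24 hpf and anti-mir-34 arrays 50.72, 40.29 and 55.56%. Embryos collected slightly further along may account for the pattern, as may a spread of stage among samples that fell unevenly on the 2 groups. Each anti-mir-34 array lay further along than the mock array of its number, but whether the numbers pair the samples was left open. With the replicate number as a block limma called 219 probe sets at 7 hpf, against 2 without it. Counted without pairs, 2 of 10 splits of the 6 arrays, the real one included, correlated at least as strongly with the age change, the highest other at 0.54. Release of miR-34 targets stays open, with adjusted p = 0.0817 for that list, which also moved with age. A change of developmental pace by the knockdown is a biological explanation that the design cannot tell apart from a difference in collection, and it was not tested.

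Maternal transcripts stood high in mock replicate 2 of 24 hpf. Of 31 probe sets outside the maternal list that were abundant at 1 hpf and low in anti-mir-34 embryos of 24 hpf, 87.1% were highest in that array among the 3 mock arrays, where chance gives 33.3% and the other 2 had 9.68 and 3.23%. RNA of eggs or of embryos that stopped early may account for this, and so may slower loss of maternal RNA in that sample, which was not tested. RNA of gastrula embryos stays open, since 0 of only 4 probe sets that could show it were highest there. Without this array the maternal list had adjusted p = 0.8 and a median of -0.12, which leaves a small lowering by the knockdown open.

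At 1 hpf, the 191 calls may reflect the injection, the clutch of eggs or the handling, none of which was tested. Each mock array of 1 hpf in turn was kept out of the fit and taken as the start of the change to mock embryos of 7 hpf. Of the lower calls, 26 of 52, 35 of 84 and 35 of 70 went with that change, at most 50%. If unrelated, 29.6, 46.5 and 40.6 calls would. The exact binomial 95% limits, with probe sets taken as independent, reached up to 64.2%, where a stage difference was taken to need 75%. The lower calls as a set thus did not follow that axis. By the labels it spans the change from maternal to zygotic transcripts. A difference of stage within the maternal phase need not follow it and stays open. Of the higher calls 36 of 37, 60 of 67 and 52 of 68 went with the change to 7 hpf, at least 76.5% (15.9, 29.9 and 28.6 calls if unrelated), so for these a later stage stays open. Over all probe sets the correlation was r = -0.03, in which uncalled probe sets dilute the calls. Whether 1 array stands behind them stays open: 75 of the 191 were kept without mock replicate 1, and in pclaf the 3 anti-mir-34 arrays stood at 6.59, 9.57 and 8.36.

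With 3 arrays against 3 there are 10 splits, so a share under 0.05 cannot be reached. The real split called 191 at 1 hpf, against 119 in the highest other, and 1 of 10 gave as many. At 7 hpf the real split called 2 and 2 of 10 gave as many. The highest other, mock replicates 1 and 2 with anti-mir-34 replicate 2 against the rest, called 228. It parts the 3 arrays least far along the way from 1 to 24 hpf (34.88, 23.32 and 40.29%) from the 3 furthest along (46.84, 50.72 and 55.56%). The samples thus hold a structure along the age axis besides the injection. At 24 hpf the real split called 2, the highest other 4, and 3 of 10 gave as many. Between mock embryos of 1 and 7 hpf it called 3722, the highest other 1, and between 7 and 24 hpf 6662, the highest other 0; 1 of 10 gave as many in both.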

How the results depend on the processing

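Damping of low values, lists with an array left out and the block together with an estimated correlation are tests chosen after the data were seen. Quantile normalization, median centring and leaving out the 1 in 3 dimmest probe sets kept all counts within 1.5 times. The deposited distributions were already nearly equal, with 75th percentiles between 5.78 and 5.8 over the arrays. Quantile normalization and median centring could therefore change little, and they do not test the choice of normalization. Without the variance trend, the counts of called probe sets were 58 at 1 hpf (191 reported), 0 at 7 hpf (2), 0 at 24 hpf (2), 8 at any age (44) and 5 for the interaction (15); in limma the zeros came with 1755 and 739 at unadjusted p below 0.05. With the 6 arrays of an age alone, limma called 0, 0 and 0 at 1, 7 and 24 hpf (1145, 1671 and 637 unadjusted). Fewer arrays then set the spread, and the groups of other ages no longer enter it. At 1 hpf, 109 of the 125 lower probe sets had a wider SD in anti-mir-34 than in mock embryos. With 16 added to the signals the counts were 22 at 7 hpf, 95 at any age and 32 for the interaction, and with 4 added 28 at 7 hpf, 0 at 24 hpf (600 unadjusted) and 81 at any age. With 16 added, 1968 rose and 2309 fell between mock embryos of 1 and 7 hpf (2103 and 1619 reported). What caused these changes was not tested.

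Leaving out 1 array gave 89 to 468 calls at 1 hpf, 0 to 403 at 7 hpf (786 to 1525 unadjusted in limma where 0), 0 to 13 at 24 hpf (568 and 632), 5 to 229 at any age, 0 to 148 for the interaction (1568), 2596 to 3943 between mock embryos of 1 and 7 hpf and 5552 to 6467 between 7 and 24 hpf. Of the 22 lists, 1 to 10 passed at 7 hpf (7 reported), 1 to 2 at 24 hpf (1), 9 to 12 between 1 and 7 hpf in mock embryos (12), 14 to 16 between 7 and 24 hpf (16) and 0 at 1 hpf (0). With an estimated correlation these numbers were 0, 0, 0 and 7, and 0 at 1 hpf. For named genes, of 3009 values under other settings 2842 kept direction and side of the threshold, 102 lost and 64 gained it (17 and 3 with 16 added), and 1 reversed: rplp0 at 1 hpf went from 0.44 to -0.22 without anti-mir-34 replicate 1, with 0.83 as the highest value, without anti-mir-34 replicate 2.

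The replicate numbers were not taken to pair the samples. The main tests, splits and relabellings therefore leave out any batch that same-numbered arrays may share. Deviations of same-numbered mock and anti-mir-34 arrays correlated at 0.03, 0.08 and 0.14 at 1 hpf, 0.06, 0.28 and 0.25 at 7 hpf and 0.01, 0.02 and 0.01 at 24 hpf, although each array matched its own number best, a hint from the data only. Without the dimmest 1 in 3 probe sets they were 0.11, 0.20 and 0.26 at 1 hpf and 0.19, 0.55 and 0.50 at 7 hpf, all over 0.1, and at 7 hpf each anti-mir-34 array lay further along the age axis than the mock array of its number; all probe sets were used, a choice made after the calls of both fits had been seen. With the replicate block the counts were 390 at 1 hpf, 219 at 7 hpf, 5 at 24 hpf, 292 at any age and 111 for the interaction, and 9 lists passed at 7 hpf, and buc passed at 24 hpf (adjusted p = 0.00381). With the block and an estimated correlation 0 lists passed at 7 hpf, 0 at 24 hpf and 0 between 1 and 7 hpf, and 8 between 7 and 24 hpf. Pseudocounts for linear values were not run, since the values are logarithms, nor were seed match tests with other site kinds or lengths of 3' untranslated regions. Dim probe sets limit precision: 22 of the 191 calls at 1 hpf lie below the median signal.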
